A study of Mus musculus with 40 samples.

How the data were processed

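The series holds 40 RNA-seq libraries of mouse uterus in 8 groups of 5, 1 group for each combination of treatment (vehicle, doxorubicin, doxorubicin with AMH, AMH alone) and harvest time (4 h or 24 h). Total RNA was extracted with a Qiagen kit and libraries were made by Novogene, per the labels. The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size) for 54532 genes, with gene names, positions and lengths, per the file headers. Build mm10 is given in the submitters' processing notes. The aligner, the counting program, the annotation release and whether counting used strand are not given in the sources used here. Of the named genes, 24 of 79 are overlapped by another gene of the table, 6 of them by a protein-coding gene (Pdia6, Nr1d1, Dbp, Ccnd1, Gm14226 and Dglucy). These, and genes with near-identical copies such as Ifit3, Hspa1b and the Sprr2 genes, are uncertain to the extent that reads could be assigned to the wrong copy. All table columns of values were mapped to a sample by name.

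The low values of each library were checked for whole reads: FPKM times gene length gave whole multiples of the smallest step in 100% of values (tolerance 0.01 reads). The rebuilt reads in genes ranged from 16251563 to 27391049 per library, and the total that the authors divided by was 0.859 to 1.06 of that sum. No 2 libraries of the same group agreed within sampling noise (lowest chi-square per degree of freedom 8.95), and the lowest Pearson correlation within a group was 0.8748. The first 3 principal components took 28.4%, 11.3% and 7.86% of the variance.

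Genes at 1 FPKM or more in at least 5 of 40 libraries were kept, which left 16226 genes, 13422 of them protein-coding, of 35714 with any value above 0. Amh itself was below this filter and was not tested. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (package data.table for reading, version 1.17.8), with an intensity trend in the prior variance and 32 residual degrees of freedom from all 8 groups in 1 fit. A fold change is on the log2(FPKM + 1) scale and understates the change of genes with low values. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of 13 comparisons, with a threshold of 0.05. A called gene rose or fell; counts adjusted over the list alone used the same p-values with adjustment within the list.

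A set of 46 gene lists (pathways, hormone responses and markers of other cell types) was fixed before the data were examined, as were the groups, tests, alternatives other than those named as added, and the rule for naming genes. Of these lists 44 had enough measured members. Lists were compared with other genes by camera, with its preset correlation between genes of 0.01. Of all list calls, those of the p53 targets for doxorubicin at 4 h and of the glucocorticoid-responsive genes for doxorubicin with AMH against doxorubicin at 24 h also passed with an estimated correlation. List scores are means of log2(FPKM + 1) over measured members, compared by exact two-sided permutation of 5 against 5 libraries (252 arrangements, smallest possible p 0.0079) and adjusted over the lists.

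The rule for named genes took, per comparison of treatments at 1 time, the 10 rising and 10 falling protein-coding called genes with the largest log2 fold change and a mean of 2 FPKM or more in the higher group, up to 4 called members with the smallest p from each list, and a fixed set called or not: Amhr2, Amh, Bmpr1a, Acvr1, Top2a, Top2b, Trp53, Cdkn1a, Mdm2, Mki67, Esr1 and Pgr. A part of these genes is printed and the rest are given as counts. Values of 1 gene that this rule took are not reported here.

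Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, only the groups compared in the fit, array weights, robust empirical Bayes, the replicate number as a block, voom on the rebuilt counts, and each library left out in turn. Added after the data were seen were marker scores of neighbouring tissue as covariates, the oestrogen-responsive score as a covariate, and leaving out the high-oestrogen or the high-oviduct libraries. Other splits of the libraries were drawn 100 times with a fixed seed. The change of doxorubicin-changed genes with AMH and the overlap of calls were computed with shared libraries divided and were simulated with no effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

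The tests were tested on simulated data. For doxorubicin against control at 4 h (15921 genes), 35.4% of genes changed 1.5-fold, 65.6% of genes changed 2-fold and 87.9% of genes changed 4-fold were recovered, and 7 of 15726 unchanged genes were called. For AMH against control at 24 h with nothing changed, 0 genes were called. For doxorubicin at 24 h (15885 genes) a changed list had camera adjusted p = 2.3e-107 and 0 of 20 random lists passed. The measure of genes moved back by AMH gave a slope of 0.00 at 24 h with no reversal (15894 genes) and -0.48 with 50% reversal (15918 genes). In these simulated data genes varied independently of each other, and each gene had the same relative spread in all libraries. The rates therefore do not cover variation shared by many genes or groups of unequal spread.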

Results

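RNA from the uterus of prepubertal mice treated on postnatal day 25 was sequenced in bulk. The mice had been given doxorubicin, an anthracycline that blocks topoisomerase II and breaks DNA, anti-Müllerian hormone (AMH), a TGF-beta family hormone that signals through its receptor Amhr2 and SMAD proteins, both agents, or vehicle (PBS or saline). The series description gives 2 weekly doses of doxorubicin at 3 mg/kg, and the labels give AMH at 0.75 mg/kg. Uteri were taken 4 h or 24 h after treatment, which made 8 groups of 5 libraries each. With 2 weekly doses of doxorubicin, differences at 4 h or 24 h may include those left by an earlier dose. Reads in genes, rebuilt from the FPKM values, ranged from 16251563 to 27391049 per library. A total of 16226 genes passed the filter on low values. Gene positions are on mouse build mm10. The labels number the libraries as biological replicates but do not say that each came from a single mouse. The p-values therefore measure the spread between these libraries, which the main limma fit pools over all 8 groups.

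Libraries within a group differed in marker genes of neighbouring tissue and in oestrogen-responsive genes. The mean log2(FPKM + 1) of 13 oviduct and ciliated cell markers lay more than 1 above the median of all libraries in 4 libraries at 4 h (control 4, doxorubicin 3 and 4, doxorubicin + AMH 5). At 24 h it did so in doxorubicin libraries 3, 4 and 5 and doxorubicin + AMH library 4. The score of 36 oestrogen-responsive uterine genes lay more than 0.6 above the median in control 24 h libraries 1, 2 and 4 (by 1.10, 1.61 and 0.92) and in AMH 24 h library 3 (by 1.00). These libraries are called high-oviduct and high-oestrogen here, and counts without them that moved by over 1.5 times are given here or with the alternatives.

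**Figure D1:**
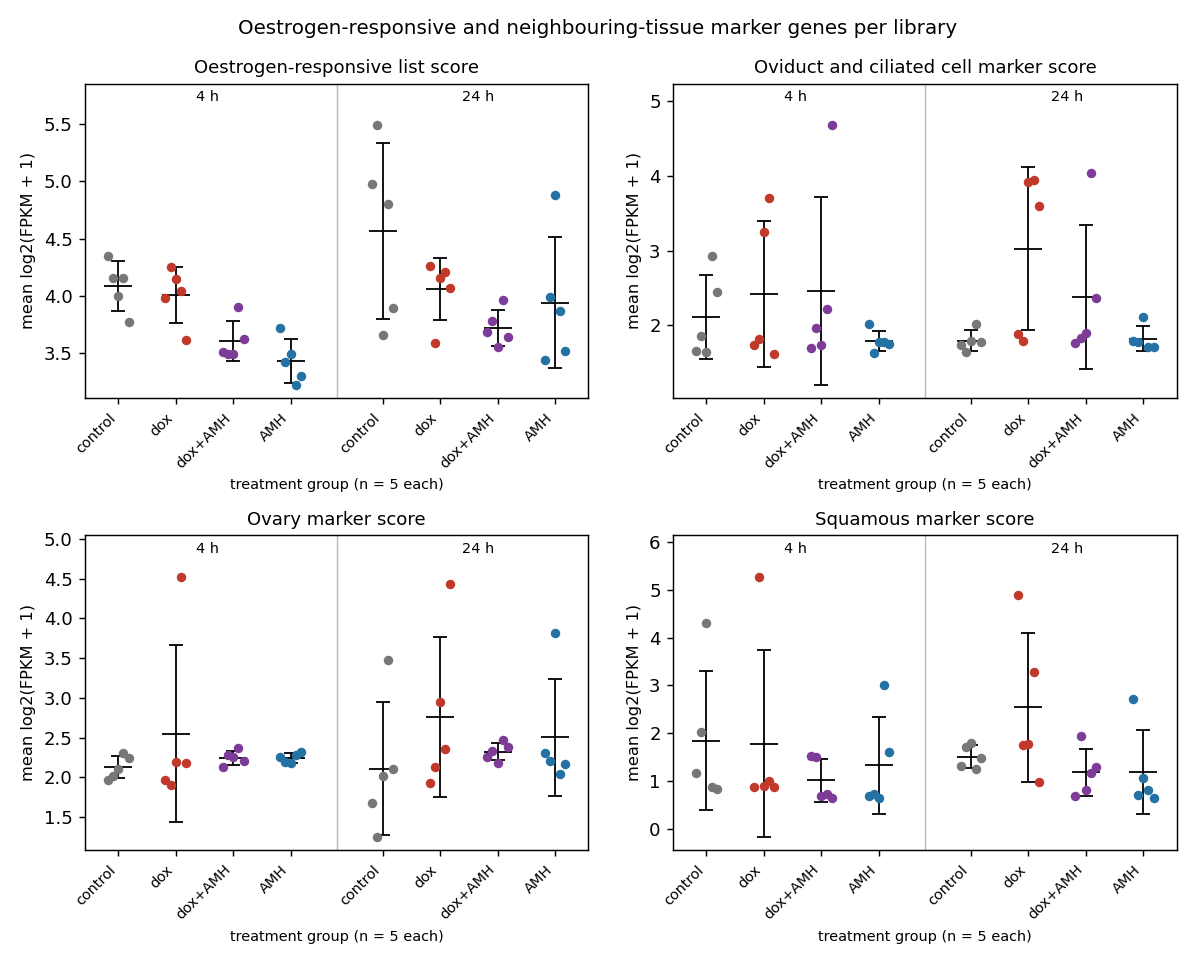
Mean log2(FPKM + 1) of the oestrogen-responsive, oviduct and ciliated cell, ovary and squamous (cervix and vagina) lists in each library, by treatment group at 4 h and 24 h. Points are libraries (n = 5 per group) and bars are mean ± SD, with an oestrogen-responsive score of 4.56 ± 0.77 in the 24 h controls and an oviduct score of 3.03 ± 1.09 in the 24 h doxorubicin group.

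The first comparison asked how doxorubicin alone differed from vehicle at 4 h. Target genes of p53, the transcription factor activated by DNA damage, rose. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes the cell cycle inhibitor p21, stood at 57.9 ± 30.3 FPKM after doxorubicin and 3.92 ± 1.25 FPKM in controls (SD, n = 5 each), a log2 change of 3.39 ± 0.36 (SE; limma adjusted p = 6.6e-07). It was higher in 5 of 5 libraries. Sesn2, a stress-induced inhibitor of mTORC1, rose from 3.04 ± 0.569 to 14.9 ± 5.56 FPKM. Trp53inp1 rose from 8.73 ± 1.33 to 32.3 ± 11.4 FPKM and Ccng1, which encodes cyclin G1, from 23.8 ± 4.16 to 81.3 ± 30.6 FPKM. Mdm2 (chromosome 10, 117688875 to 117710758), whose product degrades p53, rose by a log2 of 0.93 ± 0.15, the secreted stress factor Gdf15 by 1.84 ± 0.30 and Apaf1, a part of the apoptosome, by 0.73 ± 0.12. Of 38 p53 targets measured, 19 rose over all genes and 27 rose adjusted over the list alone (camera adjusted p = 1.5e-37; adjusted p = 0.00024 with an estimated correlation).

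Antiviral interferon-response genes were also higher at 4 h. Ifit3 (chromosome 19, 34583531 to 34588731) stood at 44.5 ± 40.6 FPKM against 5.75 ± 1.39 FPKM in controls (n = 5 each, log2 change 2.44 ± 0.46, limma adjusted p = 0.0057). Doxorubicin library 3 was at 116 FPKM and the other 4 were between 16.7 and 31.8 FPKM. Ifit1 rose from 3.73 ± 1.09 to 19.3 ± 13.7 FPKM. Of 36 interferon-response genes, 9 rose and 32 rose adjusted over the list alone (camera adjusted p = 9.9e-35). That list had adjusted p = 0.094 with an estimated correlation. Among smooth muscle markers, 1 of 14 fell, and 6 fell adjusted over the list alone (camera adjusted p = 8.2e-08; adjusted p = 0.27 with an estimated correlation). No gene of 30 in the mitosis list passed the limma test. Top2a, the doxorubicin target in dividing cells, averaged 18.3 ± 6.8 FPKM against 9.17 ± 6.25 FPKM (adjusted p = 0.54) and Mki67 13.3 ± 5.53 against 5.43 ± 3.92 FPKM (adjusted p = 0.44). The list had camera adjusted p = 6.8e-13, and adjusted p = 0.6 with an estimated correlation.

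At 4 h limma called 80 genes for doxorubicin, 63 higher and 17 lower. In all, 1955 genes had an unadjusted p under 0.05. The count was 10 with only these groups in the fit, where the calls of Ccng1, Mdm2, Apaf1, Ifit1 and Ifit3 were lost. It was 530 with library weights, 243 higher and 287 lower, and 38 without the high-oviduct libraries, where Ifit1 and Ifit3 were lost. Leaving out control library 2, 3, 4 or 5 gave 38, 32, 43 and 51 genes, and leaving out doxorubicin library 2, 3 or 5 gave 33, 28 and 191 genes.

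**Figure D2:**
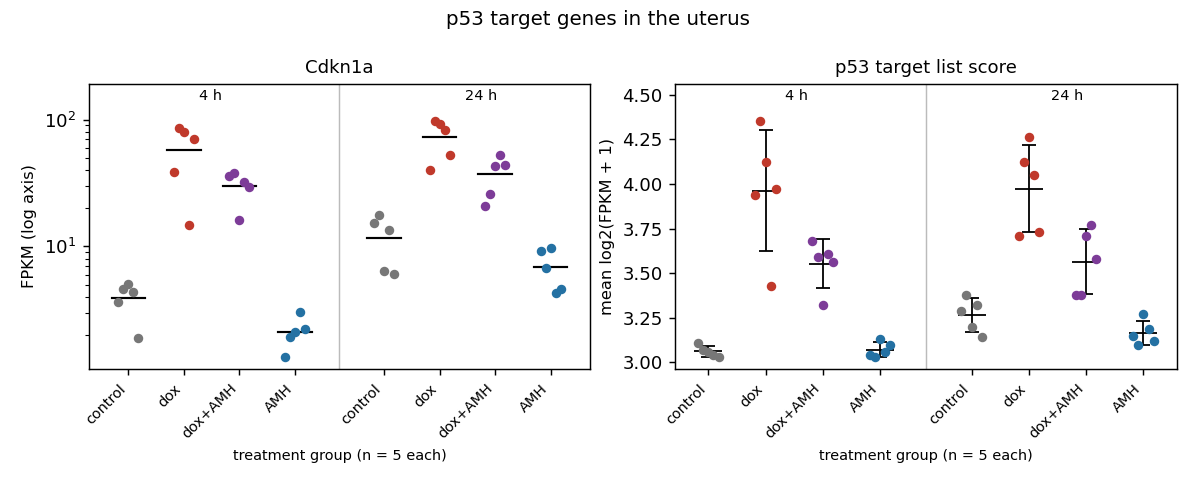
Left, FPKM of Cdkn1a on a log axis in each library by treatment group and harvest time (horizontal bars, group means). Right, mean log2(FPKM + 1) of 38 p53 targets per library (bars, mean ± SD, n = 5 per group), at 3.06 ± 0.03 in the 4 h controls, 3.96 ± 0.34 with doxorubicin and 3.55 ± 0.14 with doxorubicin + AMH.

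The same question was asked at 24 h. Among p53 targets, Cdkn1a was higher than in controls (72.9 ± 25.3 against 11.7 ± 5.24 FPKM, SD, n = 5 each, limma adjusted p = 2.6e-05). Ephx1, a detoxifying epoxide hydrolase, was higher (131 ± 42.5 against 33.3 ± 11.7 FPKM, adjusted p = 8.7e-07), and so was Bbc3, which encodes the pro-apoptotic protein PUMA (17.9 ± 6.21 against 3.92 ± 1.79 FPKM, adjusted p = 1.2e-05). Mdm2 rose by a log2 of 0.64 ± 0.15, and Trp53 itself fell from 37.1 ± 4.96 to 27.2 ± 6.59 FPKM. In this list 18 of 38 genes rose, and 22 rose adjusted over the list alone (camera adjusted p = 2.1e-12; adjusted p = 0.18 with an estimated correlation). Ifit3 rose from 5.66 ± 2.41 to 67.9 ± 33.1 FPKM and Cmpk2, an interferon-induced nucleotide kinase, from 3.1 ± 0.839 to 11.2 ± 3.77 FPKM. Of the interferon-response genes, 29 of 36 rose, 33 adjusted over the list alone (camera adjusted p = 2.4e-21; adjusted p = 0.35 with an estimated correlation). The acute-phase genes Serpina3n (24.5 ± 24.7 against 2.2 ± 1.71 FPKM) and Saa3 (7.19 ± 6.1 against 0.23 ± 0.163 FPKM) rose as well. So did the lipid carrier gene Apod (14 ± 8.55 against 1.26 ± 0.793 FPKM).

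Genes of smooth muscle and extracellular matrix were lower 24 h after doxorubicin. The smooth muscle actins Actg2 (chromosome 6, 83512905 to 83536265; 207 ± 98.1 against 662 ± 246 FPKM) and Acta2 (1270 ± 293 against 2600 ± 524 FPKM) fell, with limma adjusted p = 2.6e-05 and 4.8e-05 (n = 5 each). Calponin, Cnn1, fell likewise (136 ± 45.5 against 341 ± 89.4 FPKM, adjusted p = 4.8e-05). Of 14 smooth muscle markers, 12 fell, also adjusted over the list alone (camera adjusted p = 3.2e-11; adjusted p = 0.21 with an estimated correlation). Their score was 5.76 ± 0.26 against 6.54 ± 0.20 (exact permutation p = 0.0079, the smallest these permutations can give; 0.07 adjusted). The growth factor gene Igf1 (chromosome 10, 87858265 to 87937042) fell from 60.1 ± 25 to 16.7 ± 12.9 FPKM, and the IGF-binding protein gene Igfbp5 from 278 ± 31.4 to 129 ± 83.4 FPKM. The collagen gene Col6a3 fell from 127 ± 47.3 to 43.6 ± 22.1 FPKM and the phosphatase gene Ptpn5 from 20.1 ± 12 to 2.61 ± 1.99 FPKM. Of 37 extracellular matrix genes, 16 fell and 2 rose, 18 and 2 adjusted over the list alone (camera adjusted p = 0.00059; adjusted p = 0.62 with an estimated correlation). The 18 stroma markers, Col6a3 among them, did not fall as a list: 2 fell and 1 rose, and their score was 5.78 ± 0.24 against 5.78 ± 0.32 (camera adjusted p = 0.95). Among other cell types, the score of 5 skeletal muscle markers was lower (2.79 ± 0.33 against 3.44 ± 0.14) and that of 6 nerve and glia markers higher (1.70 ± 0.23 against 1.13 ± 0.18), each with exact permutation p = 0.0079 and 0.07 adjusted.

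Other lists also differed at 24 h. Of 16 heat shock genes, 10 fell, Dnajb1 among them (log2 change -0.72 ± 0.17), 14 adjusted over the list alone (camera adjusted p = 6.3e-06; adjusted p = 0.62 with an estimated correlation). Of 22 cholesterol synthesis genes, 9 fell, 14 adjusted over the list alone (camera adjusted p = 5e-06; adjusted p = 0.62 with an estimated correlation). Among 31 WNT and Müllerian duct genes, 9 rose, 9 adjusted over the list alone (camera adjusted p = 0.00075; adjusted p = 0.62 with an estimated correlation). Wnt11 rose by a log2 of 1.79 ± 0.41 and Wnt16 by 1.48 ± 0.35. Among 28 AMH and BMP signalling genes, 7 rose and 3 fell, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0095; adjusted p = 0.62 with an estimated correlation). The SMAD target Id3 rose from 29.5 ± 8.35 to 54.2 ± 11.3 FPKM and Atoh8 from 4.24 ± 1.9 to 10.6 ± 3.06 FPKM. Of 14 blood endothelial markers 3 rose, 8 adjusted over the list alone (camera adjusted p = 0.00065; adjusted p = 0.62 with an estimated correlation), including Vwf (5.11 ± 1.02 against 2.56 ± 1.04 FPKM). The oviduct score averaged 3.03 ± 1.09 after doxorubicin and 1.79 ± 0.14 in controls (exact permutation p = 0.048; 0.2 adjusted). The oestrogen-responsive score averaged 4.06 ± 0.27 and 4.56 ± 0.77 (exact permutation p = 0.21; 0.38 adjusted). The protease inhibitor gene A2ml1 averaged 31.4 ± 30.1 FPKM against 0.0837 ± 0.0451 FPKM (limma adjusted p = 0.046). It stood at 67, 49.9 and 39.7 FPKM in the high-oviduct doxorubicin libraries 3, 4 and 5 and at 0.0632 and 0.254 FPKM in libraries 1 and 2. Its call was lost without control library 1, 2 or 4 (adjusted p = 0.096, 0.096 and 0.091) or doxorubicin library 3, 4 or 5 (adjusted p = 0.14, 0.12 and 0.079), and without the high-oviduct libraries.

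At 24 h limma called 2984 genes for doxorubicin, 1369 higher and 1615 lower, and 1684 higher and 1132 lower after median-of-ratios scaling. The count was 25 with only these groups in the fit, where of the 24 h genes named above Cdkn1a, Ephx1, Bbc3, Ifit3 and Cmpk2 were kept. It was 73 without the high-oestrogen libraries, where these 5 and Serpina3n were kept, and 1944 without the high-oviduct libraries. It was 934, 1027, 5581 and 1130 without control library 1, 2, 3 or 4, and 1472, 1021, 1694 and 4666 without doxorubicin library 2, 3, 4 or 5.

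**Figure D3:**
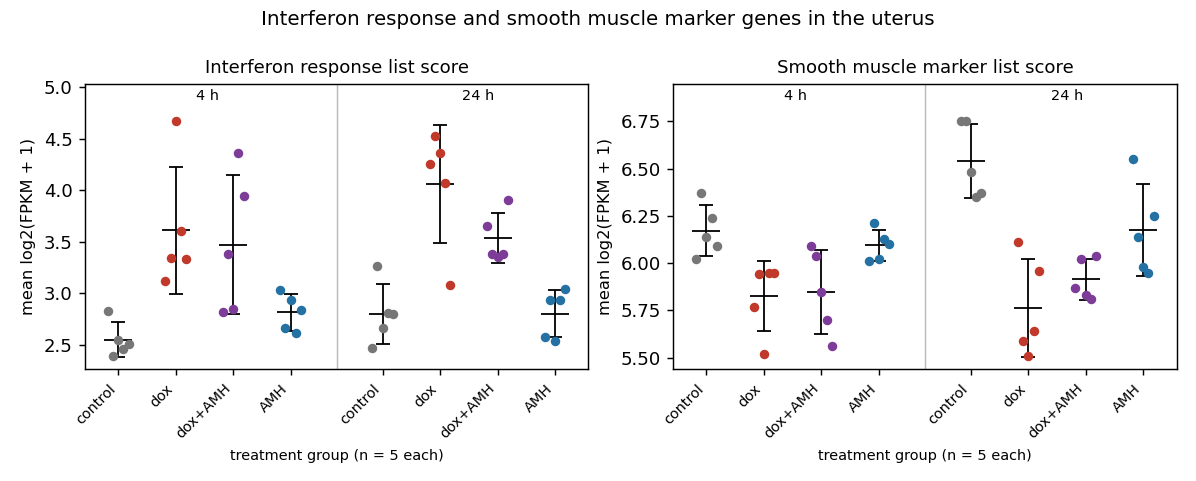
Mean log2(FPKM + 1) of 36 interferon-response genes (left) and 14 smooth muscle markers (right) in each library, by treatment group at 4 h and 24 h. Points are libraries (n = 5 per group) and bars are mean ± SD, with a smooth muscle score of 5.76 ± 0.26 in the 24 h doxorubicin group and 6.54 ± 0.20 in the 24 h controls.

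AMH given with doxorubicin was compared with doxorubicin alone, the question the design addresses most directly. At 4 h a single gene, Gm14226 (ENSMUSG00000084897, chromosome 2, 155018266 to 155027104), passed the test. It stood at 10.3 ± 3.4 FPKM with AMH and 1.83 ± 1.04 FPKM without (SD, n = 5 each, log2 change 2.01 ± 0.26, limma adjusted p = 8.2e-05) and was higher in 5 of 5 libraries. The span of nonagouti contains this gene on the same strand, so the level of Gm14226 is uncertain. Nonagouti averaged 2.35 ± 1.1 and 3.95 ± 1.65 FPKM in these groups and passed no comparison. Cdkn1a averaged 30.2 ± 8.45 FPKM with AMH and 57.9 ± 30.3 FPKM without (adjusted p = 0.71), and Mdm2 13.4 ± 1.43 and 18.6 ± 5.4 FPKM (adjusted p = 0.71). No p53 target passed over all genes and 8 of 38 fell adjusted over the list alone (camera adjusted p = 3.1e-13; adjusted p = 0.15 with an estimated correlation). The p53 score was 3.55 ± 0.14 against 3.96 ± 0.34 (exact permutation p = 0.04; 0.28 adjusted). Mitosis genes were lower as a list, with none passing alone (camera adjusted p = 4.6e-18; adjusted p = 0.46 with an estimated correlation). So were extracellular matrix genes, with 4 of 37 falling adjusted over the list alone (camera adjusted p = 2.3e-14; adjusted p = 0.17 with an estimated correlation). AMH and BMP signalling genes were higher, with 4 of 28 rising adjusted over the list alone (camera adjusted p = 0.00026; adjusted p = 0.28 with an estimated correlation).

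The 4 h count of 1 gene stood beside 1123 genes at an unadjusted p under 0.05 and 1 gene with voom on the rebuilt counts. It was 0 with only these groups in the fit, 17 with library weights, and 4, 2 and 2 without doxorubicin library 4, doxorubicin library 5 or doxorubicin + AMH library 1.

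At 24 h a small set of genes differed between doxorubicin with AMH and doxorubicin alone. Errfi1 (chromosome 4, 150853919 to 150868892), a feedback inhibitor of the EGF receptor, fell from 42.6 ± 15.3 to 16 ± 1.97 FPKM, and Wee1, the kinase that restrains entry into mitosis, from 14.3 ± 4.3 to 5.78 ± 1.4 FPKM (SD, n = 5 each, limma adjusted p = 0.0041 for both). Each was lower in 5 of 5 libraries. Gm14226 rose from 0.831 ± 0.561 to 4.37 ± 1.48 FPKM (adjusted p = 0.0041) and the transcription factor gene Gata2 from 37.2 ± 2.92 to 51.1 ± 3.2 FPKM (adjusted p = 0.0024). Id4, which encodes an inhibitor of DNA binding, rose from 20.9 ± 1.69 to 32.5 ± 4 FPKM (adjusted p = 0.018). Pmaip1, which encodes the pro-apoptotic protein NOXA, fell from 3.44 ± 1.11 to 1.17 ± 0.377 FPKM (adjusted p = 0.036) and was the single p53 target that passed over all genes. A total of 8 of 38 fell adjusted over the list alone (camera adjusted p = 5.8e-09; adjusted p = 0.33 with an estimated correlation). The p53 score was 3.57 ± 0.18 against 3.98 ± 0.25 (exact permutation p = 0.04; 0.28 adjusted). Cdkn1a averaged 37.3 ± 13.3 and 72.9 ± 25.3 FPKM (adjusted p = 0.28).

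Of 19 glucocorticoid-responsive genes, Errfi1 fell over all genes and 11 fell adjusted over the list alone (camera adjusted p = 1.3e-10; adjusted p = 0.027 with an estimated correlation). Of 30 immediate early genes 3 fell, with 9 falling and 1 rising adjusted over the list alone (camera adjusted p = 2e-05; adjusted p = 0.55 with an estimated correlation). Interferon-response genes were lower as a list, with 1 of 36 falling adjusted over the list alone (camera adjusted p = 1.3e-10; adjusted p = 0.55 with an estimated correlation), and heat shock genes likewise, with 9 of 16 (camera adjusted p = 1.4e-06; adjusted p = 0.55 with an estimated correlation). The squamous list was lower too (camera adjusted p = 0.00018; adjusted p = 0.55 with an estimated correlation), with no member passing.

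The 24 h test called 54 genes, 21 higher and 33 lower, with 2017 at an unadjusted p under 0.05. It called 0 with only these groups in the fit, 2081 with library weights and 250 without the high-oestrogen libraries. Without the high-oviduct libraries it called 71, 12 higher and 59 lower, with 18 of the 54 kept and the calls of Wee1, Id4 and Pmaip1 lost. Without doxorubicin library 1, 2, 3, 4 or 5 it called 18, 27, 23, 11 and 244 genes, and without doxorubicin + AMH library 1, 2, 3 or 5 it called 18, 7, 23 and 12. The Pmaip1 call was lost with the replicate number as a block (adjusted p = 0.061). It was lost without doxorubicin library 1, 2, 3 or 4 (adjusted p = 0.073, 0.074, 0.088 and 0.13) or doxorubicin + AMH library 1, 2, 3 or 5 (adjusted p = 0.092, 0.1, 0.069 and 0.096), and the Id4 call without doxorubicin library 4 or doxorubicin + AMH library 2 or 5 (adjusted p = 0.068, 0.065 and 0.065).

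AMH alone was compared with vehicle to see its effect in the undamaged uterus. At 4 h genes of its own pathway rose. Smad9 (ENSMUSG00000027796, chromosome 3, 54755582 to 54801257), a SMAD of the BMP branch, rose from 0.51 ± 0.22 to 2.97 ± 0.267 FPKM (SD, n = 5 each, log2 change 1.40 ± 0.14, limma adjusted p = 3.2e-07). The SMAD targets also rose, Id2 (chromosome 12, 25093799 to 25097140) from 42.8 ± 2.78 to 70.1 ± 2.57 FPKM, Id3 from 41.2 ± 4.3 to 70.8 ± 7.9 FPKM and Atoh8 from 3.16 ± 0.282 to 8.77 ± 1.09 FPKM. Of 28 AMH and BMP signalling genes, 10 rose, 10 adjusted over the list alone with 1 falling (camera adjusted p = 5.4e-05; adjusted p = 0.69 with an estimated correlation). The receptor gene Amhr2 rose from 3.39 ± 0.736 to 7.21 ± 1.4 FPKM (adjusted p = 0.021), a call lost without control library 4 (adjusted p = 0.059) or AMH library 5 (adjusted p = 0.058). Coch, which encodes a secreted matrix protein, rose from 8.52 ± 3.78 to 62.7 ± 10.7 FPKM, and the matricellular gene Ctgf from 5.17 ± 0.787 to 17.5 ± 1.88 FPKM. The AP-1 gene Jun rose from 37.5 ± 2.65 to 77.2 ± 6.12 FPKM and Gm14226 from 2.28 ± 0.995 to 9.14 ± 2.56 FPKM.

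S phase and cholesterol synthesis genes fell 4 h after AMH. The replicative helicase genes Mcm2 (3.68 ± 0.265 against 16.6 ± 7.34 FPKM) and Mcm5 (4.16 ± 0.785 against 26.3 ± 13.6 FPKM) fell, with limma adjusted p = 0.0072 and 0.0089 (n = 5 each). Ccnd1, which encodes cyclin D1, fell from 34.3 ± 5.09 to 15.4 ± 1.42 FPKM (adjusted p = 0.0054). In the S phase list 17 of 30 genes fell, 27 adjusted over the list alone (camera adjusted p = 3.5e-10; adjusted p = 0.69 with an estimated correlation). In the DNA repair list 11 of 39 fell, 17 adjusted over the list alone (camera adjusted p = 4e-05; adjusted p = 0.69 with an estimated correlation). Of 22 cholesterol synthesis genes 16 fell, 19 adjusted over the list alone (camera adjusted p = 1.4e-09; adjusted p = 0.69 with an estimated correlation). Among them was Sqle, squalene epoxidase, at 2.82 ± 0.437 against 12.1 ± 2.82 FPKM. Calr (99.5 ± 17.1 against 357 ± 80 FPKM) and Pdia6 (35.7 ± 3.01 against 118 ± 31.5 FPKM), which encode chaperones of the endoplasmic reticulum, were lower. The endoplasmic reticulum and integrated stress list went both ways, with 11 genes lower and 5 higher of 24, 14 and 5 adjusted over the list alone (camera adjusted p = 0.0055; adjusted p = 0.69 with an estimated correlation). Igf1 fell from 39.3 ± 8.77 to 12.7 ± 2.56 FPKM and Ptpn5 from 8.77 ± 3 to 0.96 ± 0.161 FPKM. The extracellular matrix list had 14 lower, Col6a3 among them, and 1 higher of 37, 18 and 1 adjusted over the list alone (camera adjusted p = 0.00028; adjusted p = 0.69 with an estimated correlation). Of 10 mesothelium markers 3 fell, Lrrn4 and Upk3b among them, 6 adjusted over the list alone (camera adjusted p = 0.0054; adjusted p = 0.69 with an estimated correlation). Of 37 ribosomal protein genes, 15 rose, Rpl23 among them (423 ± 41.7 against 292 ± 27.9 FPKM), 26 adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.69 with an estimated correlation). Of 19 clock genes 8 rose, Per1 among them, 12 adjusted over the list alone (camera adjusted p = 5e-04; adjusted p = 0.69 with an estimated correlation). The oestrogen-responsive score was 3.43 ± 0.19 with AMH and 4.09 ± 0.22 in controls (exact permutation p = 0.0079; 0.025 adjusted).

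At 4 h limma called 3250 genes for AMH alone, 1482 higher and 1768 lower, and 1689 higher and 1683 lower after median-of-ratios scaling. With the oestrogen-responsive score as a covariate it called 128. Of the genes named here Smad9, Atoh8, Ctgf, Jun, Gm14226, Calr, Pdia6, Ptpn5, Lrrn4 and Upk3b were kept with it. The score did not overlap between these groups (3.22 to 3.72 with AMH, 3.77 to 4.35 in controls), so this covariate can also remove effects of AMH. Igf1 and Ccnd1, which lost their calls, are themselves members of the score. With only these groups in the fit limma called 5885, and without control library 1, 2 or 4 it called 2008, 1700 and 2050.

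**Figure D4:**
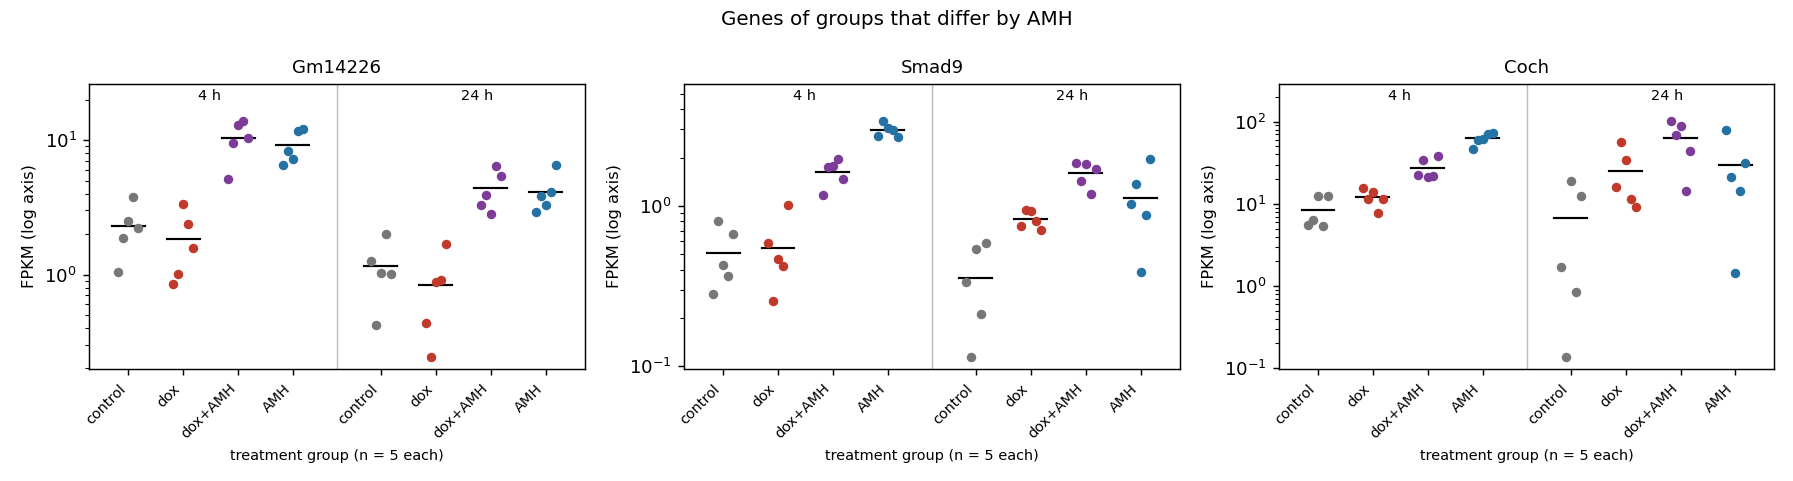
FPKM of Gm14226, Smad9 and Coch on log axes in each library, by treatment group at 4 h and 24 h. Points are libraries (n = 5 per group) and horizontal bars are group means, with Smad9 at 2.97 ± 0.267 FPKM (SD) 4 h after AMH alone and 0.51 ± 0.22 FPKM in the 4 h controls.

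At 24 h after AMH alone Errfi1 was lower, at 18.7 ± 4.02 against 54.4 ± 11.9 FPKM in controls (SD, n = 5 each, log2 change -1.48 ± 0.21, limma adjusted p = 0.00072). Also lower were Cyr61, a matricellular immediate early gene (10.7 ± 2.86 against 39.2 ± 24.6 FPKM, adjusted p = 0.0061), and Nfil3, a repressor in the clock (11.2 ± 1.11 against 24.8 ± 4.76 FPKM, adjusted p = 0.014). Id2 rose from 30.9 ± 7.66 to 50.3 ± 7.35 FPKM (adjusted p = 0.014) and Gm14226 from 1.15 ± 0.577 to 4.14 ± 1.44 FPKM (adjusted p = 0.024). Of the AMH and BMP signalling genes 4 of 28 rose, with 11 rising and 1 falling adjusted over the list alone (camera adjusted p = 3e-05; adjusted p = 0.38 with an estimated correlation). Of the WNT and Müllerian duct genes 2 of 31 rose, 11 adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.41 with an estimated correlation). Of 16 heat shock genes 1 fell, 14 adjusted over the list alone (camera adjusted p = 1.9e-11; adjusted p = 0.38 with an estimated correlation). Of 37 extracellular matrix genes 3 fell, 12 adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.67 with an estimated correlation). Amhr2 averaged 4.72 FPKM with AMH and 2.74 FPKM in controls (adjusted p = 0.2).

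The 24 h test of AMH alone called 75 genes, 31 higher and 44 lower, with 3058 at an unadjusted p under 0.05. With a pseudocount of 0.1 it called 50 higher and 39 lower. It called 3 with only these groups in the fit and 5 without the high-oestrogen libraries. Errfi1 was kept in both while Cyr61, Nfil3, Id2 and Gm14226 were not. It called 10, 9, 1926, 19 and 691 without control library 1 to 5 in turn and 21, 2180, 10 and 25 without AMH library 2, 3, 4 or 5. Calls were lost for Gm14226 without control library 1 or 2 or AMH library 2, 4 or 5 (adjusted p = 0.063, 0.14, 0.053, 0.082 and 0.082). They were lost for Id2 without control library 2 or 4 or AMH library 2 or 4 (adjusted p = 0.073, 0.05, 0.051 and 0.075), and for Nfil3 without control library 1 or AMH library 4 (adjusted p = 0.063 and 0.068).

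Doxorubicin with AMH was also set against vehicle. At 4 h Cdkn1a (30.2 ± 8.45 against 3.92 ± 1.25 FPKM) and Ccng1 (54.9 ± 9.69 against 23.8 ± 4.16 FPKM) were higher. So were Id2 (75.6 ± 10.9 against 42.8 ± 2.78 FPKM), Smad9 (1.62 ± 0.308 against 0.51 ± 0.22 FPKM) and Gm14226 (10.3 ± 3.4 against 2.28 ± 0.995 FPKM), all with limma adjusted p between 0.00021 and 0.011 (SD, n = 5 each). Of the p53 targets 4 rose, with 18 rising and 1 falling adjusted over the list alone (camera adjusted p = 2.8e-10; adjusted p = 0.33 with an estimated correlation). Of the interferon-response genes 4 rose, 28 adjusted over the list alone (camera adjusted p = 1.2e-19; adjusted p = 0.33 with an estimated correlation). Lower were Retnla, a marker of alternatively activated macrophages (0.935 ± 1.03 against 10.2 ± 4.14 FPKM), the mast cell protease gene Cma1 (0.766 ± 0.424 against 3.23 ± 0.989 FPKM) and the lectin gene Mgl2 (3.12 ± 1.21 against 7.41 ± 1.36 FPKM). Of 6 mast cell markers 1 fell, 4 adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.33 with an estimated correlation). The mean scores of macrophage markers (2.88 ± 0.25 against 3.20 ± 0.21) and dendritic cell markers (3.06 ± 0.35 against 3.62 ± 0.18) were also lower, given here without a test. Their libraries overlapped, at 2.51 to 3.17 against 2.95 to 3.52 for macrophage and 2.59 to 3.46 against 3.41 to 3.83 for dendritic cell markers. Of 37 extracellular matrix genes 3 fell, 14 adjusted over the list alone (camera adjusted p = 1.9e-10; adjusted p = 0.33 with an estimated correlation). The test called 64 genes, 35 higher and 29 lower. It called 2364 with library weights, 766 with only these groups in the fit and 14 without the high-oviduct libraries, where Smad9 was lost. Without control library 1, 2 or 4 it called 20, 16 and 16, and without doxorubicin + AMH library 2 or 5 it called 35 and 17.

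By 24 h doxorubicin with AMH differed from vehicle in p53, interferon, AMH and BMP signalling and smooth muscle genes. Cdkn1a (37.3 ± 13.3 against 11.7 ± 5.24 FPKM), Ephx1 (107 ± 16.5 against 33.3 ± 11.7 FPKM) and Ifit3 (40 ± 11.7 against 5.66 ± 2.41 FPKM) were higher (SD, n = 5 each; limma adjusted p = 0.0017, 4e-06 and 0.00022). Of 38 p53 targets 15 rose and 2 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 0.0032; adjusted p = 0.74 with an estimated correlation). Of 36 interferon-response genes 18 rose, 21 adjusted over the list alone (camera adjusted p = 1.6e-06; adjusted p = 0.74 with an estimated correlation). Id2, Id3 and Smad9 rose by a log2 of 0.97 ± 0.14, 1.32 ± 0.17 and 0.94 ± 0.14, and Ptch1, a receptor of the hedgehog pathway, by 1.06 ± 0.17. Coch rose from 6.82 ± 8.49 to 63.1 ± 34.6 FPKM. The AMH and BMP list had 13 genes higher and 4 lower of 28, the same counts adjusted over the list alone (camera adjusted p = 0.00057; adjusted p = 0.71 with an estimated correlation). In all, 16 of 31 WNT and Müllerian duct genes rose, with 16 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.71 with an estimated correlation).

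Falling groups at 24 h of doxorubicin with AMH included mitosis genes, 22 of 30 and 28 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.77 with an estimated correlation). S phase genes fell too, 13 of 30 and 17 adjusted over the list alone (camera adjusted p = 3e-05; adjusted p = 0.77 with an estimated correlation). Among the second was Rrm2, a subunit of ribonucleotide reductase, at 1.83 ± 0.929 against 16.5 ± 16.1 FPKM (SD, n = 5 each). Heat shock genes fell in 15 of 16 cases, 15 adjusted over the list alone (camera adjusted p = 8.6e-10; adjusted p = 0.71 with an estimated correlation), and smooth muscle markers in 11 of 14, 13 adjusted over the list alone (camera adjusted p = 2.5e-06; adjusted p = 0.71 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 19 of 28, 25 adjusted over the list alone (camera adjusted p = 2.6e-07; adjusted p = 0.71 with an estimated correlation), and extracellular matrix genes in 21 of 37 with 2 rising, 22 and 3 adjusted over the list alone (camera adjusted p = 1.1e-06; adjusted p = 0.71 with an estimated correlation). Oestrogen-responsive genes fell in 14 of 36 cases with 1 rising, the same counts adjusted over the list alone (camera adjusted p = 0.005; adjusted p = 0.74 with an estimated correlation). Sprr2f, a member of a family with near-identical copies and therefore uncertain, averaged 6.8 ± 8.26 against 632 ± 1060 FPKM. The iron-binding lipocalin gene Lcn2 averaged 9.53 ± 8.74 against 315 ± 381 FPKM. Actg2 fell to 198 ± 31 FPKM, Igf1 to 16.2 ± 9.98 FPKM, Ptpn5 to 1.15 ± 0.865 FPKM and Top1, topoisomerase I, from 18 ± 3.57 to 9.88 ± 1.99 FPKM.

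That test called 5566 genes, 2555 higher and 3011 lower, and 3099 higher and 2336 lower after median-of-ratios scaling. It called 1019 with only these groups in the fit, 498 with the oestrogen-responsive score as a covariate and 119 without the high-oestrogen libraries, where Ifit3, Coch, Igf1, Actg2, Rrm2, Sprr2f and Lcn2 were lost. Without control library 1 or 2 it called 3550 and 2901.

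Whether AMH acted differently with and without doxorubicin was tested as an interaction. Neither time gave a gene with limma. It called 0 at 4 h, with 2356 at an unadjusted p under 0.05, and 0 at 24 h, with 675. Voom also called 0 at each time. At 4 h the interaction term of p53 targets was lower as a list, with 7 of 38 lower adjusted over the list alone (camera adjusted p = 8e-06; adjusted p = 0.64 with an estimated correlation). So was that of ribosomal protein genes, with 18 of 37 (camera adjusted p = 7.8e-17; adjusted p = 0.64 with an estimated correlation). At 24 h the term of smooth muscle markers was higher, with 7 of 14 higher adjusted over the list alone (camera adjusted p = 4.2e-11; adjusted p = 0.39 with an estimated correlation). That of interferon-response genes was lower (camera adjusted p = 1.4e-09; adjusted p = 0.66 with an estimated correlation). With library weights the counts were 1667 at 4 h and 69 at 24 h, and with only the groups of each time in the fit the 4 h count was 1241. Leaving out doxorubicin library 4 or 5 or AMH library 3 at 4 h, or doxorubicin library 5 at 24 h, gave 1 gene.

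Whether doxorubicin acted differently at 4 h and 24 h was tested in the same way and gave 2 genes, with 1580 at an unadjusted p under 0.05. Egr1, an immediate early transcription factor, was lower by -0.40 on the log2 scale at 4 h and higher by 1.27 at 24 h (23 ± 7.36 against 8.83 ± 2.27 FPKM, n = 5 each), a difference of 1.67 ± 0.31 (limma adjusted p = 0.047). Ccdc117 was higher by 0.19 at 4 h and lower by -0.43 at 24 h, a difference of -0.62 ± 0.11 (adjusted p = 0.04). The Egr1 call was lost, with adjusted p from 0.052 to 0.18, without any 1 of 4 h control libraries 1 to 5, 4 h doxorubicin libraries 1, 2 and 4, 24 h control libraries 1, 2, 4 and 5 and 24 h doxorubicin libraries 2, 3 and 4. The Ccdc117 call was lost, with adjusted p from 0.05 to 0.15, without any 1 of 4 h control libraries 2 to 5, 4 h doxorubicin libraries 1, 2, 4 and 5, 24 h control libraries 1 and 2 and 24 h doxorubicin libraries 2, 3 and 4. Without the high-oviduct libraries 13 genes were called and neither of these was kept. Both calls were also lost with the replicate number as a block and with only the groups compared in the fit. They were lost too with the oestrogen-responsive score as a covariate and without the high-oestrogen libraries. The count reached 4 without 4 h doxorubicin library 3 and 8 without 24 h doxorubicin library 5. Mitosis genes had lower terms as a list with none passing (camera adjusted p = 1.7e-14; adjusted p = 0.58 with an estimated correlation). The change of the AMH effect on doxorubicin between the times gave 0 genes with limma and 0 with voom, with 593 at an unadjusted p under 0.05, and 1 gene without 4 h doxorubicin library 2 or 24 h doxorubicin + AMH library 3. Ribosomal protein genes had higher terms (camera adjusted p = 3.1e-24; adjusted p = 0.31 with an estimated correlation) and glucocorticoid-responsive genes lower ones, 3 of 19 adjusted over the list alone (camera adjusted p = 1.3e-07; adjusted p = 0.12 with an estimated correlation).

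The vehicle groups at 24 h and 4 h were compared as the background of every contrast between times. Clock genes differed. Nr1d1 (chromosome 11, 98767932 to 98775333), which encodes REV-ERB alpha, stood at 10.6 ± 5.98 FPKM at 24 h and 51.6 ± 11.4 FPKM at 4 h, and Dbp at 6.64 ± 4.59 and 48.2 ± 10.7 FPKM. Arntl, which encodes BMAL1, stood at 4.28 ± 0.466 and 1.6 ± 0.297 FPKM and Nfil3 at 24.8 ± 4.76 and 4.23 ± 0.628 FPKM (SD, n = 5 each; limma adjusted p between 4.3e-09 and 7.7e-06). Nr1d1 overlaps Thra and Dbp overlaps Sphk2, so their levels are uncertain. Of 19 clock genes 5 rose and 8 fell, 7 and 9 adjusted over the list alone (camera adjusted p = 0.18). Heat shock genes rose, 8 of 16 and 11 adjusted over the list alone (camera adjusted p = 1.7e-12; adjusted p = 0.22 with an estimated correlation). Glucocorticoid-responsive genes rose too, 7 of 19 with 8 rising and 1 falling adjusted over the list alone (camera adjusted p = 3e-05; adjusted p = 0.22 with an estimated correlation). Errfi1 rose from 15.1 ± 1.45 to 54.4 ± 11.9 FPKM. The test called 1188 genes, 695 higher and 493 lower, and 509 higher and 587 lower after median-of-ratios scaling. It called 95 with only these groups in the fit and 477 without the high-oestrogen libraries. Without 4 h control library 3 or 5 it called 713 and 538, and without 24 h control library 1, 2 or 3 it called 545, 483 and 2414.

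**Figure D5:**
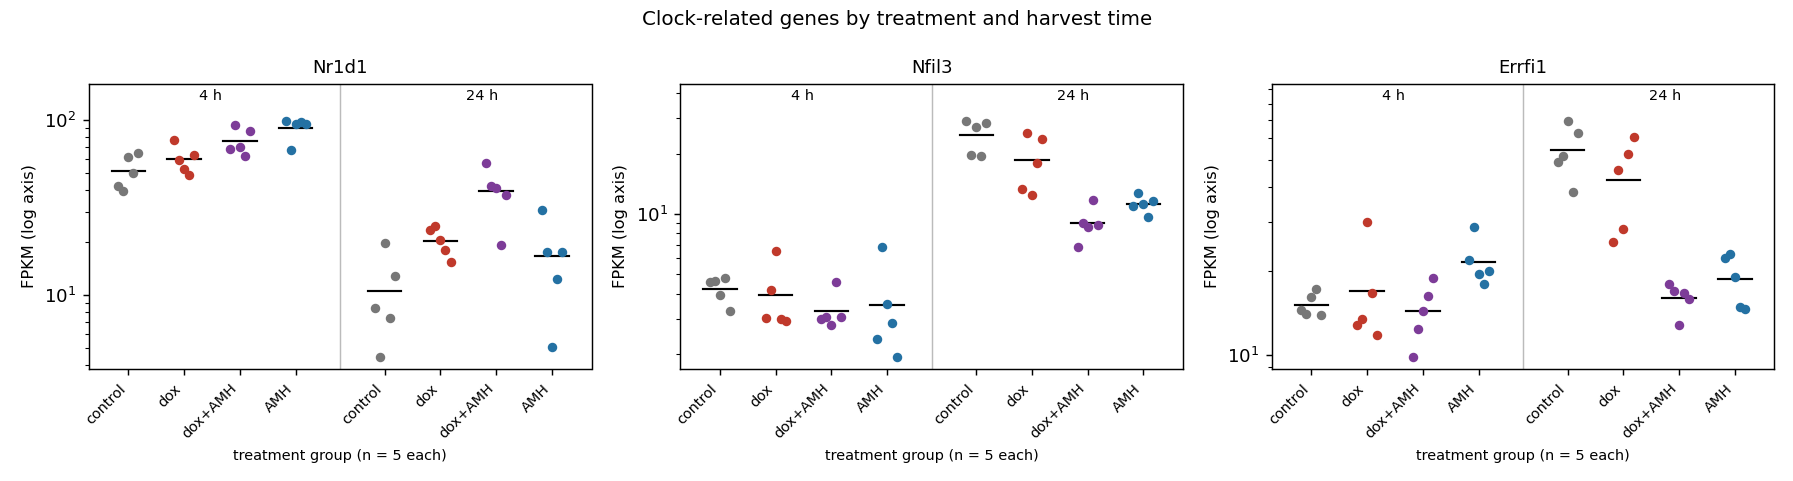
FPKM of Nr1d1, Nfil3 and Errfi1 on log axes in each library, by treatment group at 4 h and 24 h. Points are libraries (n = 5 per group) and horizontal bars are group means, with Errfi1 at 54.4 ± 11.9 FPKM (SD) in the 24 h controls and 16 ± 1.97 FPKM with doxorubicin + AMH at 24 h.

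Whether AMH moved the doxorubicin-changed genes back was measured with doxorubicin libraries that were not shared, since a common group alone makes such changes look opposite. The doxorubicin libraries were divided in all 10 ways into 3 that, with the controls, chose the changed genes and 2 that were compared with doxorubicin + AMH. At 4 h, over a mean of 58.6 genes (9 to 262), 70.7% changed in the opposite direction with AMH (34.7% to 100%). The slope of the AMH change on the doxorubicin change across genes was -0.24 (-0.64 to 0.01). Simulated data without an AMH effect gave 47.8% and 0.01. Across all genes the divided changes had a correlation of 0.03 and a covariance of 0.004, against 0.02 and 0.003 simulated. At 24 h, over a mean of 1719 genes (127 to 3984), 49.1% changed in the opposite direction and the slope was -0.04 (-0.41 to 0.20), against 54.2% and -0.03 in simulated data (correlation 0.04 and covariance 0.008 across all genes, against -0.04 and -0.007). With shared doxorubicin libraries the slopes were -0.35 over 80 genes at 4 h and -0.13 over 2984 genes at 24 h, against -0.11 and -0.13 simulated. With shared libraries the covariances across genes were -0.021 and -0.020 against -0.024 and -0.031 simulated.

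Genes called against vehicle overlapped between doxorubicin with and without AMH, which share their controls. At 4 h 13 genes were higher in both, against 0.136 expected of independent lists, and 5 lower in both, against 0.0304. At 24 h 960 were higher in both (215.6 expected), 1219 lower in both (299.7 expected) and 1 opposite. With the controls divided into 2 and 3, the shared genes averaged 1.15 higher and 0 lower at 4 h, and 94.25 higher and 131.8 lower at 24 h (20.91 and 32.37 expected). Simulated unchanged groups against common controls shared 0 higher and 0.01 lower at 4 h, and 0 of each at 24 h. They had almost no calls to share: 0.01 and 0.23 higher and 0.03 and 4.5 lower at 4 h, without and with AMH. At 24 h they had 5.18 and 0.01 higher and 3.67 and 0.01 lower. These shared counts therefore cannot show how much overlap common controls create among many calls. The correlation of log2 changes across genes, which are not independent replicates, was 0.64 at 4 h and 0.81 at 24 h with common controls, against 0.46 and 0.50 simulated. With divided controls it was 0.36 and 0.59, against 0.01 and -0.05 simulated. The covariance with common controls was 0.056 and 0.173 against 0.025 simulated at each time.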

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

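The tests against other splits of the libraries, the stratified permutation of the p53 and other list scores and the p53 score with tissue covariates at 4 h were chosen after the results were seen, as were the covariate settings themselves. The tests along the oestrogen-responsive genes, the shares of calls lost with tissue covariates and the splits behind the slopes of doxorubicin-changed genes were fixed before their results were seen.

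The first pattern weighed is the large count of genes in 3 comparisons whose mean oestrogen-responsive scores also differed, by -0.51, -0.84 and -0.66 in the order given below. For doxorubicin at 24 h this difference did not pass the permutation test (4.06 ± 0.27 against 4.56 ± 0.77). Doxorubicin + AMH against vehicle at 4 h also had a lower mean score (3.60 ± 0.18 against 4.09 ± 0.22) but only 64 called genes. A candidate explanation is that the groups lay at different points of a variation that also exists within groups, such as the hormonal state of single animals. It was tested by taking the trend of each called gene on that score within 30 libraries of groups not compared, leaving the list's own genes out. The trend gave the observed direction for 83% of 2980 genes for doxorubicin at 24 h, for 89.7% of 5551 genes for doxorubicin with AMH against vehicle at 24 h and 94.1% of 3244 genes for AMH at 4 h, while the observed changes were 3.92, 2.23 and 2.46 times the predicted size, so the sizes are accounted for in part. The explanation stays open for all 3, and an effect of treatment on the same genes was not told apart from it.

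The second pattern is the signal of oviduct, ovary and squamous epithelium in some libraries. Abundant markers of each may come from neighbouring tissue taken with the uterus: Ovgp1 reached 790 FPKM in doxorubicin + AMH 4 h library 5 (median of all libraries 1.87), Krt5 reached 1150 FPKM in doxorubicin 4 h library 2 (median 2.45), Inha reached 99.4 FPKM in AMH 24 h library 3 (median 7.33) and Hsd3b1 reached 55 FPKM in doxorubicin 4 h library 4 (median 0), although 8 of 13 oviduct, 6 of 12 squamous and 3 of 5 ovary markers have a median of 1 FPKM or more here and no other list holds any of them. With marker scores of oviduct, ovary, squamous tissue and fat as covariates, 95 of the 269 genes that rose 2-fold or more 24 h after doxorubicin lost their call or that size (35.3%), between the bounds of 10% and 50% set for deciding. Of the 19 p53 targets that rose at 4 h, 2 were lost (10.5%), which those bounds also leave open, but the p53 score difference kept a share of 1.00 of its size (0.90 before and after), which argues against tissue as its cause. Treatment effects on these tissues were not tested.

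The third pattern is the lower p53 target score when AMH was given with doxorubicin, -0.41 at each time. Grouping by chance within each harvest time was tested by an exact stratified permutation of the mean of both (p = 0.0013 over 63504 arrangements, 0.02 adjusted over the 44 lists), which argues against it, but each time alone gave 0.28 adjusted, averaging the times was chosen after both were seen, and 9 of the 44 lists passed: the NRF2, senescence, oestrogen-responsive, mitosis, glucocorticoid-responsive and extracellular matrix lists and macrophage markers (-0.28, 0.049 adjusted) were lower as well, and AMH and BMP signalling higher. With the tissue covariates the mean was -0.44, a ratio of 1.07, which argues against neighbouring tissue. Left open are a lower share of macrophages, which was not tested, the oestrogen-responsive score, lower by -0.40 with AMH at 4 h (exact permutation p = 0.024; 0.28 adjusted), and the dose of doxorubicin that each uterus received, which was not tested. Over all genes Pmaip1 at 24 h was the single p53 target that passed, and the list was not called with an estimated correlation at either time.

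Splits of the same libraries into other groups of equal size gave these counts of called genes, 100 splits each with the real one included. By the bar of fewer than 5 splits as large, doxorubicin at 4 h passed (80 genes, highest other 18, 1 split as large). So did AMH at 4 h (3250, highest other 7, 1 as large) and doxorubicin + AMH against vehicle at 4 h (64, highest other 1, 1 as large). In these the real count was above that of every other split drawn, which argues against chance. The bar was also passed by doxorubicin + AMH against doxorubicin at 24 h (54, highest other 122, 3 as large). Doxorubicin + AMH against vehicle at 24 h (5566, highest other 7245, 3 as large) passed it too. The change of the doxorubicin effect with time had 4 splits as large (2, highest other 134), but as an interaction its splits cannot decide, as given below. These later counts lay within the range of the other splits, so chance cannot be excluded for them. It cannot be excluded for doxorubicin at 24 h (2984, highest other 6086; 6 as large) and doxorubicin + AMH against doxorubicin at 4 h (1, highest other 72; 11 as large). Nor can it be for AMH at 24 h (75, highest other 7285; 11 as large) and the vehicle groups between times (1188, highest other 3801; 5 as large). The 3 comparisons with 0 genes cannot exclude it either, as all 100 splits reach 0. Their highest others were 36 and 4293 for the interaction of the agents at 4 h and 24 h and 364 for the change of the AMH effect with time. Splits that call many times the real count, such as 7285 against 75, point to a structure of the samples other than treatment. For the interactions the splits mixed libraries of all groups in the contrast. Differences between treatments or times can enter those counts, such as 134 against 2, so the splits cannot decide on chance there. More than 2 times the real count was called by 1 other split for doxorubicin + AMH against doxorubicin at 24 h and by 2 for the change of the doxorubicin effect with time. As 13 comparisons were read at this bar, doxorubicin + AMH at 24 h passes it only narrowly, both against doxorubicin and against vehicle. For doxorubicin-changed genes, 10 of 100 regroupings gave a slope as negative at 4 h (-0.24, lowest other -0.45) and 27 of 100 at 24 h (-0.04, lowest other -0.31), so chance cannot be excluded at either time.

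Single libraries stood far from the other 4 of their group in 25 of the 208 groups of values examined. Chance alone marks about 1 in 20 where values are independent and normally distributed. The single-gene values were FPKM without logs, and the same libraries enter many of these groups of values. The count of 25 therefore cannot be set against that rate. Among list scores, doxorubicin 24 h library 2 had an oestrogen-responsive score of 3.59 (others 4.07 to 4.26), and doxorubicin + AMH 24 h library 3 a mitosis score of 2.03 (0.97 to 1.27). Doxorubicin 24 h library 5 had a cholesterol score of 3.17 (2.32 to 2.54) and a heat shock score of 5.99 (5.32 to 5.50), and doxorubicin + AMH 24 h library 4 had a cholesterol score of 3.58 (2.39 to 2.68) and a heat shock score of 5.77 (4.98 to 5.10). Oviduct scores were 4.68 in doxorubicin + AMH 4 h library 5 (1.69 to 2.22), 4.04 in doxorubicin + AMH 24 h library 4 (1.76 to 2.36) and 2.11 in AMH 24 h library 3 (1.71 to 1.79). Ovary scores were 4.52 in doxorubicin 4 h library 4 (1.90 to 2.19) and 3.81 in AMH 24 h library 3 (2.04 to 2.31). Squamous scores were 5.27 in doxorubicin 4 h library 2 (0.86 to 0.99) and 2.72 in AMH 24 h library 1 (0.65 to 1.05).

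Among single genes, FPKM values far from the rest of the group were 74.5 for Id2 in doxorubicin + AMH 24 h library 3 (others 53.7 to 58.8), 116 for Ifit3 (16.7 to 31.8) and 30 for Errfi1 (11.8 to 16.6) in doxorubicin 4 h library 3. Igf1 stood at 39.5 in doxorubicin 24 h library 5 (9 to 13.2). Gata2 stood at 51.8 in AMH 24 h library 2 (45.3 to 47.2). Sprr2f stood at 90.3 in doxorubicin 4 h library 2 (7.06 to 18.9), 2500 in control 24 h library 2 (7.3 to 369), 21.5 in doxorubicin + AMH 24 h library 4 (1.77 to 4.36) and 195 in AMH 24 h library 3 (4.53 to 12.8). Calr stood at 441 in doxorubicin 24 h library 5 (145 to 205), 455 in doxorubicin + AMH 24 h library 4 (112 to 175) and 385 in AMH 24 h library 3 (152 to 203).

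The interaction test of the doxorubicin effect between 4 h and 24 h called Egr1 (by 1.67 on the log2 scale) and Ccdc117 (by -0.62). Of 20 fits with 1 library left out, 5 kept the Egr1 call and 7 the Ccdc117 call. Amh, below the filter and in no comparison, stood at 11.9 FPKM in doxorubicin 4 h library 4 and 9.2 FPKM in doxorubicin 24 h library 5, against 0.0408 to 2.32 FPKM in the vehicle libraries. These 2 libraries also had the highest ovary marker scores of all 40 (4.524 and 4.433, against 3.808 or less).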

How the results depend on the processing

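The settings with tissue covariates, with the oestrogen-responsive score as a covariate, and without high-oestrogen or high-oviduct libraries were chosen after the data were seen; for each changed value the cause was not tested unless fewer libraries show it by construction. Of 116 called results for named genes, 115 were kept with a pseudocount of 0.1, 109 without a filter, 109 of 109 with a filter at 5 FPKM, 116 with scaling, array weights or robust empirical Bayes, 113 with voom or the replicate block and 110 with tissue covariates. The numbers were 91 with the oestrogen-responsive score, 79 without high-oestrogen libraries and 103 without high-oviduct libraries. They were 70 with only the groups compared in the fit and 103 in every case of 1 library left out, and none changed sign. Where the oestrogen-responsive score differs between the groups compared, as for AMH at 4 h, that covariate can also remove effects of treatment. Reads in genes were at least 16251563 in every library. With only the groups compared, the fit has fewer residual degrees of freedom by construction. This does not account for counts that rose in that setting, such as those of AMH and of the interaction of the agents at 4 h. The main fit gives each gene a common spread for all groups, but the groups were unequal. The S phase score had an SD of 0.97 in the 24 h controls and 0.11 in the 4 h AMH group. Library weights were 0.232 to 0.985 and 1.24 to 2.21 in these groups. P-values of the main fit can thus be too small where groups spread widely and too large where they spread little. Unequal spread was not tested as the cause of the moved counts.

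Gene counts that moved by over 1.5 times are given by comparison. Doxorubicin against control at 4 h (80) gave 48 without a filter, 10 with only the groups compared, 530 with array weights and 182 with tissue covariates. It gave 164 with the oestrogen-responsive score, 148 without high-oestrogen and 38 without high-oviduct libraries, and 28 to 191 with 1 library left out. At 24 h (2984) the values were 1855 without a filter, 25 with only the groups compared, and 6875 with weights. They were 818 with the oestrogen-responsive score, 73 without high-oestrogen and 1944 without high-oviduct libraries, and 934 to 5581 with 1 library left out.

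Doxorubicin + AMH against doxorubicin at 4 h (1) gave 3 without a filter, 0 with only the groups compared, 17 with weights, 7 without high-oestrogen and 2 without high-oviduct libraries, and 1 to 4 with 1 library left out. At 24 h (54) it gave 35 with a pseudocount of 0.1, 30 without a filter, 0 with only the groups compared, and 2081 with weights. It gave 29 with tissue covariates, 91 with the oestrogen-responsive score, 250 without high-oestrogen libraries, and 7 to 244 with 1 library left out. AMH against control at 4 h (3250) gave 5885 with only the groups compared, 6835 with weights and 128 with the oestrogen-responsive score, and 1700 to 3325 with 1 library left out. At 24 h (75) it gave 29 without a filter, 3 with only the groups compared, and 4094 with weights. It gave 187 with tissue covariates, 13 with the oestrogen-responsive score, 5 without high-oestrogen libraries, and 9 to 2180 with 1 library left out.

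Doxorubicin + AMH against control at 4 h (64) gave 766 with only the groups compared, 2364 with weights, 383 with tissue covariates, 688 without high-oestrogen and 14 without high-oviduct libraries, and 16 to 63 with 1 library left out. At 24 h (5566) it gave 1019 with only the groups compared, 8545 with weights, 498 with the oestrogen-responsive score, 119 without high-oestrogen libraries, and 2901 to 7132 with 1 library left out. The interaction of the agents at 4 h (0) gave 1241 with only the groups compared, 1667 with weights, 21 with tissue covariates, 10 without high-oestrogen libraries and 0 to 1 with 1 library left out. At 24 h (0) it gave 69 with weights and 0 to 1 with 1 library left out.

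The change of the doxorubicin effect with time (2) gave 1 without a filter, 0 with only the groups compared, and 1063 with weights. It gave 0 with the oestrogen-responsive score, 0 without high-oestrogen and 13 without high-oviduct libraries, and 0 to 8 with 1 library left out. The change of the AMH effect (0) gave 1 with a filter at 5 FPKM, 1 with scaling, 3 with weights, 2 without high-oviduct libraries and 0 to 1 with 1 library left out. Vehicle at 24 h against 4 h (1188) gave 95 with only the groups compared, 3124 with weights, 477 without high-oestrogen libraries, and 483 to 2414 with 1 library left out.

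The direction with more called genes turned in these cases (higher and lower genes). For doxorubicin at 4 h it turned with weights (243 and 287). At 24 h it turned with scaling (1684 and 1132), only the groups compared (19 and 6), the oestrogen-responsive score (411 and 407), without high-oestrogen (39 and 34) or high-oviduct libraries (974 and 970), and without control library 1 (490 and 444) or 4 (574 and 556) or doxorubicin library 1 (1171 and 1134), 2 (762 and 710) or 3 (515 and 506). For doxorubicin + AMH against doxorubicin it turned at 4 h without doxorubicin library 4 (1 and 3). At 24 h it turned with weights (1065 and 1016), without high-oestrogen libraries (134 and 116), and without doxorubicin library 2 (17 and 10), 4 (7 and 4) or 5 (134 and 110) or doxorubicin + AMH library 2 (4 and 3), 3 (13 and 10) or 4 (41 and 30). AMH alone turned at 4 h with scaling (1689 and 1683), and at 24 h with a pseudocount of 0.1 (50 and 39) and only the groups compared (2 and 1). Doxorubicin + AMH against vehicle turned at 4 h with a filter at 5 FPKM (21 and 23), only the groups compared (302 and 464), weights (1119 and 1245), without high-oestrogen libraries (331 and 357), and without control library 3 (25 and 27) or doxorubicin + AMH library 4 (24 and 39). At 24 h it turned with scaling (3099 and 2336) and only the groups compared (532 and 487). The vehicle groups between times turned with scaling (509 and 587).

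Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated above 0.1 in 18 of 60 pairs (-0.715 to 0.388, median 0.019), and 7 of 40 libraries lay closest to their own number. With the replicate block the change of the doxorubicin effect with time gave 0 genes and the change of the AMH effect 1, and the other 10 counts moved by less than 1.5 times. Vehicle at 24 h against 4 h gave 458. As the blocks lay within harvest times, that value depends on the reference block of each time and cannot be set beside the main count.

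Lists called by camera, out of 44, fell with an estimated correlation from 14 to 1 for doxorubicin at 4 h, 21 to 0 at 24 h, 24 to 0 for doxorubicin + AMH against doxorubicin at 4 h, 20 to 1 at 24 h, 14 to 0 for AMH at 4 h and 14 to 0 at 24 h. They fell from 21 to 0 for doxorubicin + AMH against control at 4 h, 17 to 0 at 24 h, and 14 to 0 and 15 to 0 for the interaction of the agents at 4 h and 24 h. They fell from 24 to 0 and 14 to 0 for the changes of the doxorubicin and AMH effects with time, and 14 to 0 for vehicle between times. Fry, which does not compare a list with other genes, called 4 and 11, 0 and 2, 12 and 7, 6 and 16, 0 and 0, 0 and 0, and 5 in that order. Shared genes of doxorubicin with and without AMH fell from 13 to 1.15 higher and from 5 to 0 lower at 4 h, and from 960 to 94.25 higher and from 1219 to 131.8 lower at 24 h, with controls divided, where fewer libraries enter each test. With a pseudocount of 0.1, 2 genes were lower in both at 4 h.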

Other observations

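The genes and comparisons of this part were chosen after their values were seen. AMH was given in 2 backgrounds that share no libraries, with doxorubicin (against doxorubicin) and without (against vehicle). Both comparisons used the same estimate of the spread of each gene, so their lists are not fully independent and the expected counts may be too low. At 24 h, 3 genes were higher in both, against 0.0401 expected of independent lists, and 10 were lower in both, against 0.0895, with 0 in opposite directions. They included Gm14226 and Pcif1, both higher, and Errfi1, Cyr61, Nfil3, Tiparp, Plod2, Frzb, Banp, 1700017B05Rik, Gm45819 and Gm42547, all lower. Each of the 20 libraries of these groups, left out alone, moved a shared count by over 1.5 times. Higher and lower counts were 1 and 3, 1 and 5, 12 and 20, 2 and 6, and 4 and 16 without control library 1 to 5. They were 1 and 7, 4 and 4, 2 and 5, 1 and 3, and 6 and 12 without doxorubicin library 1 to 5, and 1 and 4, 1 and 2, 3 and 4, 5 and 10, and 1 and 3 without doxorubicin + AMH library 1 to 5. Without AMH library 1 to 5 they were 2 and 6, 1 and 5, 12 and 19, 1 and 3, and 1 and 4. Without the high-oestrogen libraries 0 were higher and 2 lower, and without the high-oviduct libraries 2 and 3. Errfi1 was shared in each of these cases, and Gm14226 was not without control library 1 or 2, AMH library 2, 4 or 5, or the high-oestrogen libraries. At 4 h the pair of comparisons shared Gm14226, against 0.0913 genes expected, and shared it in every such case; 2 genes were shared without control library 2, doxorubicin library 5 or doxorubicin + AMH library 1, and 7 without the high-oestrogen libraries. The correlation of the 2 sets of log2 changes across 16226 genes, which are not independent replicates, was 0.42 at each time.

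At 4 h, 58 genes separated all 10 libraries given AMH from all 10 not given it, and at 24 h 6 did, where chance gives 0.18 per time. Gm14226 did so at both times: 5.17 to 13.8 FPKM against 0.853 to 3.77 FPKM at 4 h, and 2.83 to 6.57 FPKM against 0.243 to 2.02 FPKM at 24 h. The others at 4 h included Smad9 (1.17 to 3.37 against 0.255 to 1.02 FPKM), Coch (21.4 to 73.6 against 5.34 to 15.8 FPKM) and Tgfbi, a matrix protein gene induced by TGF-beta (167 to 303 against 52 to 151 FPKM). At 24 h Errfi1 (12.8 to 23.1 against 25.5 to 69.1 FPKM) and Cyr61 (4.67 to 13.8 against 14.5 to 81.9 FPKM) were lower in every library given AMH.

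Nfil3 and Cyr61, which were higher in vehicle at 24 h than at 4 h, were lower at 24 h where AMH was given. The 24 h vehicle libraries enter both changes, so a fall against vehicle is expected in part from this choice of genes. Nfil3 averaged 24.8 FPKM in vehicle, 18.6 with doxorubicin, 11.2 with AMH and 9.01 with both, and Cyr61 averaged 39.2, 20.3, 10.7 and 7.63 FPKM in that order. Against doxorubicin alone the Nfil3 call (limma adjusted p = 0.036) was lost without doxorubicin library 2 or 4 or doxorubicin + AMH library 1, 2, 3 or 5 (adjusted p from 0.076 to 0.11), and the Cyr61 call (adjusted p = 0.029) without doxorubicin library 1, 2, 3 or 4 or doxorubicin + AMH library 1, 2 or 3 (adjusted p from 0.057 to 0.099). Without the high-oviduct libraries both were lost against doxorubicin (adjusted p = 0.064 for Nfil3 and 0.1 for Cyr61), as with tissue covariates (0.081 and 0.095). Against vehicle both were lost without the high-oestrogen libraries (0.19 and 0.59). Errfi1 had the same pattern, at 54.4 FPKM in vehicle at 24 h and 15.1 at 4 h, and 18.7 with AMH and 16 with both at 24 h. Nr1d1, lower in vehicle at 24 h than at 4 h, went the other way with both agents. It averaged 39.4 against 10.6 FPKM in vehicle at 24 h (limma adjusted p = 9.9e-05). With AMH alone Nr1d1 ranged from 5.02 to 30.7 FPKM, against 4.41 to 19.8 FPKM in vehicle. No explanation of these patterns was tested.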
